A study of Macaca mulatta with 12 samples.

How the data were processed

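Blood was drawn from the femoral vein and mononuclear cells were isolated by gradient centrifugation, per the labels' protocols. Cells were captured with the 10x Chromium 5' kit (v2 chemistry), and a polyA gene expression library and, derived from it, a BCR library were sequenced on an Illumina NovaSeq. The series held 12 libraries of 6 animals, an expression and a BCR library of each. The labels gave the sex and the batch of each animal, with both males in batch 1 and all 4 females in batch 2. Animals are named by sex and by their order within it, and no treatment group was given.

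The authors deposited the expression data as counts, a single table of raw UMI counts of 22584 listed genes in 13849 cells, of which 2669 genes were at 0 in every cell. Cell Ranger 9.0.1, R 4.3.1 and Seurat 5.0.1 were named in the submitters' processing notes. The genome build, the annotation and the immunoglobulin reference were not given in the sources used here. The deposited cell table gave the library of each cell, its UMI count, the percent of its UMIs from mitochondrial and from ribosomal protein genes as computed by the authors, a doublet call and the authors' annotation of 13 clusters. The column sums of the count table were checked and equalled the UMI count in the cell table. UMIs per cell ran from 500 to 39732, mitochondrial percent reached 9.99, and all 13849 cells carried the doublet call Singlet, so no further filter on cells and no doublet caller was applied. The cluster named Contamination (525 cells) was left out, and the 12 other names were used as deposited, without expanding their abbreviations. Names with MBC were taken as memory subtypes. The BCR files, per the file headers, held counts of UMIs and reads per contig, gene names and sequences of contigs.

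Unnamed identifiers (5813 of the listed genes, 14.9% of UMIs) matched no name in the reference tables at hand and were left out of library sizes and tests, as were 23 named immunoglobulin genes (0.186% of UMIs). The design written before the data were examined had named immunoglobulin genes only, but unnamed identifiers can include them, and the alternative with both kept in library sizes is among those below. Genes that share sequence with near-identical copies (RPS4Y1 and RPS4Y2, HBA, CCL4L1, KIR3DL0 and neighbouring IGHV genes) are uncertain, because the counting could split their UMIs. XIST, planned as a check gene, was not among the named genes used.

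Cells are not replicates, so raw counts were summed per animal and class, and sums of fewer than 10 cells were left out. A cell's class came from the constant gene of its productive heavy chain, for B cells with exactly 1 such chain, and 158 contigs had no constant gene. B cells with no heavy chain (2636) or with 2 (282) stayed out of comparisons by class. Sums were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test) in R 4.3.3, with the animal as a block and Benjamini-Hochberg adjustment over genes, and genes with adjusted p under 0.05 are called. Both classes come from the same animals, which is the source of the pairing. Sums held 168 to 1845 cells for switched against unswitched cells, 80 to 1149 within memory cells, 15 to 770 for IgA against IgG, 138 to 877 for kappa against lambda and 563 to 3048 for males against females, the last without a block. Library sizes of the sums ran from 110494 counts in the IgA comparison to 1.71e+07 in that of the sexes. Female 2, with 8 IgA cells, was left out of the IgA comparison. Log2 differences of subtypes are against the mean of the log2 values of the other subtypes, Naive B cells 2 and 3 included. CPM are means over animals ± SD. Spread between animals is biological, with technical noise of each library in it.

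Named genes followed a rule fixed before the data were examined. In each direction it took up to 6 genes with the largest log2 change among called genes with a mean log2 CPM of 4 or more and the same direction in every animal (no overlap for the sexes), and from each gene list the 2 measured members with the smallest p, or up to 4 for the naive, memory, atypical and homing lists. For subtypes it took up to 4 per direction, and for IGHV genes the called ones and the 5 most used. Y-linked check genes and the subtype markers were also fixed. The 21 gene lists, written from textbook knowledge before the data were examined, covered naive, transitional, memory, atypical, plasma and secretory, germinal centre, marginal zone and homing genes, BCR signalling, TNF family receptors and NF-kB, MHC class II and presentation, interferon response, cell cycle, immediate early and stress, ribosomal proteins, oxidative phosphorylation, and markers of T cells, NK cells, monocytes, dendritic cells, and platelets and red cells. Some genes stand on more than 1 list, such as GZMB among NK and dendritic cell markers. Lists were tested with camera, at a preset correlation of 0.01 and at an estimated one, and with fry (limma 3.58.1), adjusted over lists within a comparison.

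A clone was defined by animal, IGHV gene, IGHJ gene and the nucleotide sequence of the heavy CDR3. IGHV genes with 20 or more clones were tested with edgeR on clone counts. Divergence was the number of differences per 100 bases over FWR1 to FWR3 from the nearest sequence of the same gene, length and animal that 3 or more distinct CDR3s of unswitched cells shared (320 sequences in all). A common mutated sequence would be missed by it, and cells without such a sequence have no value, which in female 4 left 25% of switched cells. Per-animal values were compared with exact two-sided sign-flip permutation tests, where the smallest possible p is 0.03125 with 6 animals, 0.0625 with 5 and 0.125 with 4. The share of cells in clones of 2 or more cells was taken after thinning both classes to the same number of cells, averaged over 100 draws. Subtype shares of the sexes were compared with exact permutation tests over 15 splits. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these, and matplotlib 3.10.9 for figures.

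The fits were tested on simulated data with the real means and library sizes and 200 changed genes. At 2-fold and 4-fold, edgeR recovered 91.4% and 100% of changed genes for switched against unswitched cells (9559 and 9555 genes tested), 98.0% and 100% within memory cells (9154 and 9135), 68.1% and 96.1% for IgA against IgG (6204 and 6217), 98.9% and 100% for kappa against lambda (9140 and 9151), and 0% and 74.2% for the sexes (11007 and 10976). For a subtype at 2-fold it recovered 89.9% (8774 genes), and for IGHV genes 25% and 91.7% of 12 changed genes (70 and 71 tested). All 6 checks of the sign-flip test, the adjustment of p-values and the divergence measure passed, those of divergence on simulated receptors. The kappa share, CDR3 length and clone share were not checked in this way.

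Alternatives tried were DESeq2 1.42.0, no filter on low counts, immunoglobulin and unnamed genes kept in library sizes, 30 or more cells per sum, no animal block, batch 2 only, leaving out each animal in turn, leaving out 4137 cells with any UMI of CD3D, CD3E, NKG7, LYZ or S100A8, the heavy chain of most UMIs in cells with several, and heavy contigs of 3 or more UMIs. For the repertoire they were all barcodes of the BCR libraries, cells in place of clones, other minimums of shared sequences, memory subtypes only, the deposited clonotype and no thinning. Settings added after seeing the data were leaving out Naive B cells 2 and 3 (clusters 10 and 11), blocking by animal and memory subtype, C-MBC 2 only for IgA against IgG, and divergence within memory cells with references from Naive B cells 1. Cell types transferred by the authors from a reference were only tabulated by subtype, and reads per contig and light chain genes other than their class were not used here. A few genes that could have been named as examples are not reported here.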

Results

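B cells in the blood of 6 healthy, unmanipulated juvenile rhesus macaques of Indian origin were profiled by single-cell sequencing, with a 5' gene expression library and a matching B cell receptor (BCR) library from each animal. The 2 males made up batch 1 and the 4 females batch 2, so sex and batch could not be separated. The expression table held 13849 cells, of which 13324 carried the name of 1 of 12 annotated B cell subtypes and 525 were annotated as contamination and left out of the comparisons. Total unique molecular identifiers (UMIs) per animal ranged from 3642517 in female 4 to 20023015 in female 3, and the median per cell from 4018 in male 2 to 6736 in female 2. Female 4 contributed 563 B cells and the other 5 animals 1596 to 3048 each. The BCR libraries held 28676 contigs in 15041 barcodes, 12586 of which were in the expression table. Exactly 1 productive heavy chain of known class was found in 10293 B cells, of which 2380 were class-switched (IgG, IgA or IgE) and 7913 unswitched (IgM or IgD).

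To describe the annotated subtypes, each was compared with the mean of the others in counts summed per animal. Leading genes were ranked among called genes with a mean log2 CPM of 4 or more and the same direction in every animal tested. CD11c+ MBC 1 made up 16.3% ± 5.12 of B cells, M-MBC 1 15.5% ± 5.24, M-MZL BC 12.7% ± 7.05, Naive B cells 1 12.3% ± 4.33, CD11c+ MBC 2 11.2% ± 6.12 and C-MBC 1 9.88% ± 2.21 (mean ± SD, n = 6 animals). Smaller shares were held by M-MBC 2 (6.71% ± 3.66), Activated B cells (6.01% ± 3.84), C-MBC 2 (4.25% ± 2.48), Naive B cells 2 (3.33% ± 2.09), Naive B cells 3 (1.06% ± 0.839) and antibody-secreting cells (0.799% ± 1.27). Naive B cells 1 were led by TCL1A, an AKT co-activator of early B cell stages (log2 difference 5.34 ± 0.22 SE), RFLNB (4.29 ± 0.17) and FCER2, the low-affinity IgE receptor (3.92 ± 0.17). The CD11c+ subtypes shared KCNIP3, a calcium-binding transcriptional repressor, at 5.34 ± 0.23 in the CD11c+ MBC 1 and 6.37 ± 0.21 in the CD11c+ MBC 2 cells. CR2, which encodes complement receptor CD21, was lower in both (-4.02 ± 0.68 and -5.02 ± 0.78). ITGAX, which encodes CD11c itself, was at 893 ± 271 CPM (counts scaled to library size) in CD11c+ MBC 2 and 737 ± 219 in CD11c+ MBC 1, against 11.3 ± 4.19 in Naive B cells 1. C-MBC 1 were led by the transcriptional co-activator EYA2 (3.95 ± 0.19) and the lipase MGLL (3.35 ± 0.24), and C-MBC 2 by SSPN (3.94 ± 0.21), TMEM273 (3.80 ± 0.19) and VPREB3 (3.78 ± 0.30). M-MBC 1 were led by AEBP1 (2.93 ± 0.19) and the inhibitory receptor LILRB1 (2.90 ± 0.21), and M-MBC 2 by MAST4 (3.22 ± 0.39) and the signalling adaptor TYROBP (2.85 ± 0.15). M-MZL BC were led by NIBAN3 (4.04 ± 0.20), RASSF6 (3.93 ± 0.23) and VPREB3 (3.80 ± 0.26). Activated B cells expressed the chemokine gene CCL3 (5.79 ± 0.26), CSF1 (4.67 ± 0.24) and MYC (3.91 ± 0.19) above the other subtypes. Antibody-secreting cells, tested in 3 animals with 43 cells, expressed JCHAIN, the joining chain of polymeric immunoglobulin (7.15 ± 0.28), MZB1 (5.76 ± 0.21) and PRDM1, which encodes Blimp-1 (5.40 ± 0.35).

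Gene lists fixed before the data were examined were then counted in each subtype. In Naive B cells 1, 19 of 20 measured genes of the naive list were higher, and in antibody-secreting cells all 15 of the plasma and secretory list. Higher in C-MBC 1 were 16 of 19 of the memory list and all 17 of the immediate early and stress list. The atypical list was higher for 13 of 16 genes in CD11c+ MBC 1 and 14 of 16 in CD11c+ MBC 2, and also for 15 of 16 in M-MBC 2. In Activated B cells 13 of 14 genes of the list of TNF family receptors and NF-kB were higher, whereas 9 of 14 were lower in CD11c+ MBC 1. Markers of natural killer (NK) cells were higher for 6 of 8 genes in M-MZL BC and 5 of 8 in CD11c+ MBC 2. T cell markers were higher for 6 of 13 in Activated B cells, and platelet and red cell markers for 3 of 4 in M-MBC 1. Monocyte markers were higher for 3 of 5 in both CD11c+ MBC 1 and M-MBC 1. By edgeR's quasi-likelihood test, called genes per subtype (adjusted p under 0.05) ranged from 1819 of 9410 in M-MBC 2 to 4170 in Naive B cells 2. Their sum was 33497 with the animal as a block and 18532 without it. The subtypes were annotated on the same expression values, so these differences are a description and no independent evidence.

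Naive B cells 2 and 3 stood apart from Naive B cells 1 in RNA content. Ribosomal protein transcripts made up 2.76% ± 3.37 and 3.70% ± 4.22 of their UMIs, against 21.6% ± 2.46 in Naive B cells 1, and mitochondrial transcripts 4.11% ± 1.46 and 4.69% ± 1.33, against 2.39% ± 0.701. A BCR contig was found in 28.9% ± 16.7 and 32.9% ± 18.6 of their cells, against 96.2% ± 1.60. All 23 measured genes of oxidative phosphorylation and 20 of 21 ribosomal protein genes were lower in both than in the mean of the other subtypes. Naive B cells 2 expressed EYA2 (3.57 ± 0.26) and MEGF11 (3.38 ± 0.27) above the others. Of the naive list 4 of 20 genes were higher and 5 lower in Naive B cells 2, and of the atypical list 9 of 16 were higher and 1 lower. Naive B cells 3, tested in 4 animals with 112 cells, expressed the sialyltransferase gene ST6GALNAC3 (6.37 ± 0.33). Median UMIs per cell averaged 3188 and 1946, against 4482 in Naive B cells 1.

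To ask how the annotated subtypes differed in their receptors, the BCR libraries were read by subtype. Class-switched cells made up 80.3% ± 6.27 of C-MBC 2, 78.5% ± 11.5 of C-MBC 1 and 68.5% ± 17.2 of CD11c+ MBC 2, but 29.5% ± 19.9 of CD11c+ MBC 1 and 0.455% ± 0.557 of Naive B cells 1. M-MBC 1, M-MBC 2, M-MZL BC and Activated B cells were mostly unswitched, with 9.08% ± 4.65, 12.4% ± 7.11, 3.37% ± 1.67 and 6.95% ± 7.30 switched cells. IgA was the class of 26.9% ± 3.10 of C-MBC 2 and 1.78% ± 2.06 of C-MBC 1 cells, while antibody-secreting cells, with fewer than 10 cells of known class per animal, held 15 IgA, 10 IgG, 5 IgM and 2 IgE cells in all. Divergence of the IGHV region from the nearest common sequence of the animal, an estimate of somatic mutation, was taken in animals with 10 or more cells with such a reference. It was 5.33 ± 1.19 differences per 100 bases in C-MBC 1 (n = 6), 5.01 ± 0.435 in C-MBC 2 (n = 5) and 4.33 ± 1.18 in CD11c+ MBC 2 (n = 5). It was 3.29 ± 0.997 in Activated B cells (n = 5), 2.33 ± 0.362 in M-MBC 2 (n = 5) and 2.45 ± 0.337 in M-MZL BC (n = 6). Lower values were found in CD11c+ MBC 1 with 1.44 ± 0.784, in M-MBC 1 with 0.689 ± 0.305 and in Naive B cells 1 with 0.0873 ± 0.101 (n = 6 each), the references coming from unswitched cells, Naive B cells 1 included. Female 4 had 6 to 9 such cells in C-MBC 2, CD11c+ MBC 2, Activated B cells and M-MBC 2, and with it their means were 5.49, 4.82, 3.58 and 2.70. Heavy CDR3 regions of M-MZL BC averaged 14.9 ± 0.292 amino acids and those of Naive B cells 1 16.6 ± 0.233, a difference of -1.69 that was negative in 6 of 6 animals. Kappa light chains were carried by 56.8% ± 6.22 of M-MZL BC cells and 43.9% ± 5.09 of Naive B cells 1. Of 39 exact two-sided sign-flip permutation tests against Naive B cells 1, 20 had an unadjusted p under 0.05 and 0 an adjusted p under 0.05 (smallest adjusted p = 0.0609), the smallest p that 6 animals allow being 0.03125. Among the subtypes tested in all 6 animals, the switched share was higher than in Naive B cells 1 in every animal for 8 subtypes, divergence for 4 and the kappa share for 2. CDR3 length was lower in every animal for 6. Divergence was also higher in 5 of 5 animals for the 4 subtypes in which it was tested without female 4.

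**Figure D1:**
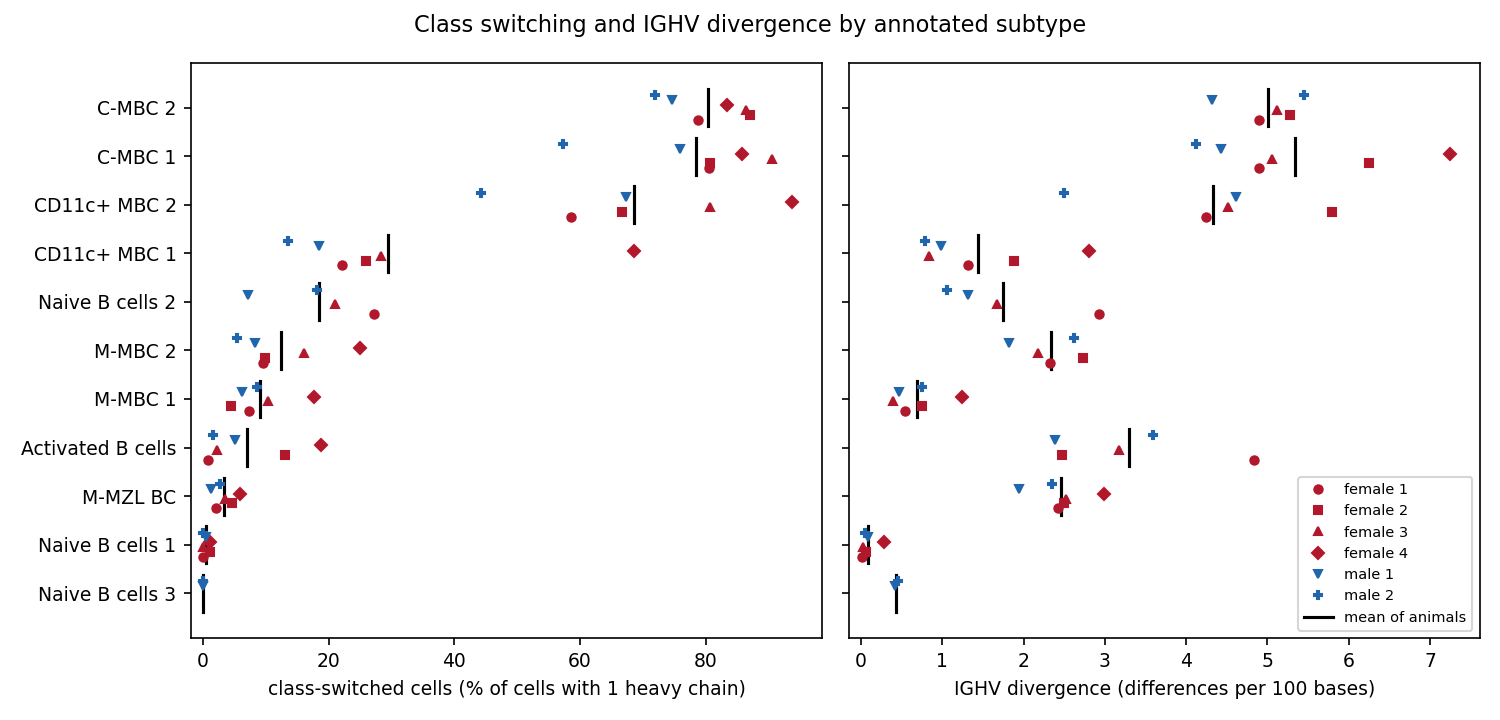
Percent of class-switched cells among cells with 1 heavy chain (left) and IGHV divergence in differences per 100 bases (right) by annotated subtype, with a point per animal that had 10 or more such cells (right, 10 or more with a reference sequence), females in red and males in blue, and a black line at the mean of the animals. Means of the switched share run from 0.455% in Naive B cells 1, or 0 in Naive B cells 3 with 2 animals, to 80.3% in C-MBC 2, while divergence in M-MBC 2 (2.33), M-MZL BC (2.45) and Activated B cells (3.29) lies above that of CD11c+ MBC 1 (1.44).

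To assess which genes went with class switching, switched and unswitched B cells of the same animals were compared, with the class taken from the BCR library. EYA2, a transcriptional co-activator of the eyes absent family, showed the largest increase, from 30.9 ± 20.5 to 262 ± 97.5 CPM (log2 difference 3.05 ± 0.18 SE, n = 6, adjusted p = 4.2e-08 by edgeR's quasi-likelihood test). It was followed by CADM1, a cell adhesion molecule (2.74 ± 0.19), the monoacylglycerol lipase MGLL (2.45 ± 0.18) and SSPN of the dystrophin-associated complex (2.39 ± 0.19). ITGAM, which encodes the integrin CD11b (2.17 ± 0.17), and CENPF, a centromere protein (2.15 ± 0.14), came next. The largest decreases among the ranked genes were those of ST6GALNAC3, from 27.7 to 2.74 CPM (-3.36 ± 0.18), AEBP1 (-3.12 ± 0.17) and the filamin-binding protein gene RFLNB (-3.04 ± 0.15). TCL1A (-2.98 ± 0.26), TTC24 (-2.47 ± 0.16) and CCSER1 (-2.37 ± 0.22) followed. The same direction in 6 of 6 animals was a condition for naming these 12 genes, and 1775 called genes met it. In all, 2416 of 9649 genes were called, 1283 higher and 1133 lower in switched cells, and 355 of them differed by more than 1 on the log2 scale. The count was 104 without the animal as a block and 1569 without female 3.

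**Figure D2:**
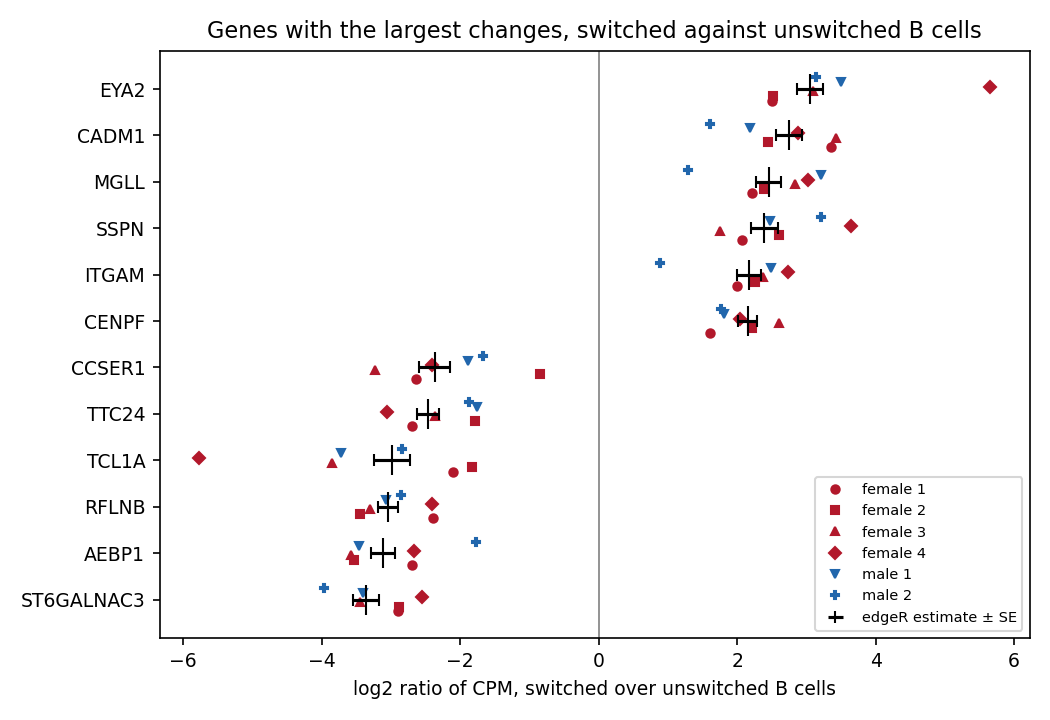
Log2 ratio of CPM in switched over unswitched B cells for 12 genes, with a point per animal, females in red and males in blue, and the edgeR estimate ± SE in black. They are those with the largest changes among called genes with a mean log2 CPM of 4 or more and the same direction in every animal. All points lie on the same side of 0 for each gene, as their selection required, and female 4 lies farthest out for EYA2, at 5.65, where the other 5 animals lie between 2.51 and 3.50.

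Genes of the naive list fell in switched cells for 13 of 20 measured members, among them the transcription factors FOXP1 (-1.20 ± 0.08) and BACH2 (-1.66 ± 0.13), and 1 rose. Of the memory list 12 of 19 rose and 3 fell, with CRIP1 at 1.11 ± 0.06, the calcium-binding protein gene S100A10 at 1.13 ± 0.08, VIM at 0.46 ± 0.05 and COCH at 4.27 ± 0.46. The plasma and secretory list rose for 7 of 15 members and fell for 1 (SEC11C 0.79 ± 0.08, PRDM1 1.18 ± 0.17). The list of MHC class II and presentation rose for 5 of 11 and fell for 1 (LGMN 1.02 ± 0.09, IFI30 0.37 ± 0.06). The list of immediate early and stress genes rose for 8 of 17 and fell for 1 (ATF3 1.02 ± 0.12, JUN 0.68 ± 0.10). Oxidative phosphorylation genes rose for 13 of 23 members and fell for 0 (COX5A 0.46 ± 0.06, UQCRQ 0.35 ± 0.06). Ribosomal protein genes fell for 14 of 21 and rose for 0 (RPS23 -0.27 ± 0.04). T cell markers fell for 3 of 11 and rose for 1 (CD8A -1.33 ± 0.21, CD3G 0.64 ± 0.13). The other fallen ones, named after their values were seen, were CD2 (-0.63 ± 0.19) and CD4 (-0.87 ± 0.26). CD2 lost its call without female 1 (-0.59) and female 2 (-0.48), and CD4 without female 1 (-0.88), female 2 (-0.79) and male 2 (-0.65). These 8 lists were called by camera with a preset correlation of 0.01, with adjusted p of 5.86e-06 for naive, 0.000147 for memory, 0.0104 for plasma, 0.0482 for MHC class II and 0.00146 for immediate early genes. It was 2.78e-05 for oxidative phosphorylation, 0.000352 for ribosomal protein genes and 0.0482 for T cell markers. None held with an estimated correlation, where the adjusted p was 0.342 for naive, memory, plasma and immediate early, 0.616 for MHC class II, 0.146 for oxidative phosphorylation and 0.570 for ribosomal protein genes and T cell markers. Over all 5 comparisons of genes camera called 27 of 102 list tests, and with an estimated correlation 0, of which 6 had an unadjusted p under 0.05, while fry, which tests whether a list moved one way, called 29.

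The other 13 lists were not called by camera in this comparison. Atypical genes rose for 9 of 16 members and fell for 4, with the phosphatase gene DUSP4 at 1.43 ± 0.17, ITGAX at 0.80 ± 0.10, CD86 at 1.06 ± 0.14 and FCRL2 at -1.67 ± 0.21, and camera's adjusted p for the list was 0.0861. Homing genes rose for 7 of 13 and fell for 3, with the integrin genes ITGB7 (0.87 ± 0.08) and ITGB2 (0.78 ± 0.10) higher and the chemokine receptor genes CXCR4 (-0.73 ± 0.10) and CCR6 (-1.12 ± 0.15) lower. Transitional genes fell for 3 of 7 and rose for 1 (MYO1C -1.08 ± 0.09, CD38 -0.67 ± 0.11), and marginal zone genes fell for 3 of 8 and rose for 2 (CR2 -1.70 ± 0.17, NOTCH2 -0.83 ± 0.10). BCR signalling genes fell for 4 of 17 and rose for 3, including the co-receptor gene CD72 at -2.35 ± 0.22 and CD79B, a chain of the receptor complex, at -1.18 ± 0.12. TNF family receptors and NF-kB fell for 6 of 14 and rose for 4 (CD40 -0.83 ± 0.12, NFKBIA -0.60 ± 0.09), with a median log2 difference of -0.14, a mean of 0.05 and camera's direction down. Interferon response genes fell for 6 of 16 and rose for 0 (HERC5 -0.91 ± 0.10, IRF7 -0.57 ± 0.12). Cell cycle genes rose for 4 of 14 and fell for 1 (MKI67 1.72 ± 0.23), and germinal centre genes rose for 1 of 8 and fell for 1 (KLHL6 0.54 ± 0.10, ELL3 -1.32 ± 0.12). Antibody-secreting cells stayed in this comparison, and those of known class were 15 IgA, 10 IgG, 2 IgE and 5 IgM cells. Within the memory subtypes, which leave them out, MKI67 was at 0.91, and at 0.86 without female 1, where the call was lost. Among markers of other cell types, NKG7 of NK cells rose (0.69 ± 0.17, and 0.49 without female 3, where the call was lost) and GNLY was at 0.35 ± 0.15 (adjusted p = 0.12 by edgeR). Of 4 monocyte markers CST3 rose (0.93 ± 0.24, and 0.68 without female 3, where the call was lost) and TYROBP fell (-1.85 ± 0.17). Of 4 dendritic cell markers 0 were called by edgeR, with 1 at an unadjusted p under 0.05. The 2 with the smallest p were ZBTB46 at 0.46 ± 0.21 (adjusted p = 0.12) and BATF3 at 0.46 ± 0.33 (0.35). Of 4 platelet and red cell markers 2 fell, PPBP (-0.42 ± 0.09) and PF4 (-0.40 ± 0.10), each lower in 5 of 6 animals. Adjusted over the list alone, the counts of risen and fallen genes became 1 and 15 for naive, 1 and 5 for transitional, 8 and 1 for plasma, 2 and 4 for marginal zone and 7 and 4 for homing. They were 4 and 7 for BCR signalling, 5 and 6 for TNF family receptors and NF-kB, 6 and 1 for cell cycle, 9 and 1 for immediate early, 15 and 0 for oxidative phosphorylation and 1 and 4 for T cell markers. They were the same as over all genes for the other 10 lists.

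To separate class switching from the share of memory cells, the comparison was repeated within the annotated memory subtypes. The classes still lay in different subtypes, since switched cells made up 78.5% of C-MBC 1 but 9.08% of M-MBC 1. Against the mean of the other subtypes, 13 of 20 naive genes were higher and 0 lower in M-MBC 1. AEBP1, a leading gene of M-MBC 1, and EYA2 and MGLL, leading genes of C-MBC 1, are among those below. Only the fit with animal and memory subtype as blocks, given below, sets class apart from subtype. CADM1 rose from 15.4 to 69.3 CPM (2.45 ± 0.15 SE, n = 6, adjusted p = 3.3e-09 by edgeR's quasi-likelihood test). EYA2 rose from 50.1 ± 27.7 to 272 ± 97.0 CPM (2.33 ± 0.11, adjusted p = 1.4e-10 by edgeR). Among genes that met the naming rule they were followed by MGLL (1.97 ± 0.13), SSPN (1.89 ± 0.16), TANC2 (1.85 ± 0.14) and ZBTB38 (1.84 ± 0.18). The largest decreases of such genes within memory cells were those of AEBP1 (-3.11 ± 0.21), the sarcomere protein gene TTN (-2.67 ± 0.12), CD72 (-2.24 ± 0.18), TYROBP (-2.20 ± 0.16) and RFLNB (-2.13 ± 0.21). Each had the same direction in 6 of 6 animals, as the naming rule required. TCL1A of the naive list (-2.30 ± 0.22) was lower in 5 of 6 animals and at 0 CPM in both classes of female 4. Of 9247 genes 1298 were called, 657 higher and 641 lower. The immediate early and stress list rose for 9 of 17 members and fell for 0 (DUSP2 1.26 ± 0.11, JUN 0.87 ± 0.11). The list of TNF family receptors and NF-kB rose for 7 of 14 and fell for 0 (CD70 0.86 ± 0.14, LTB 0.60 ± 0.10). Homing genes rose for 6 of 13 and fell for 3, and the risen ones included ITGA4 (0.87 ± 0.11) and CCR7 (0.72 ± 0.10). Memory genes rose for 10 of 18 and fell for 2 (CRIP1 0.83 ± 0.05, S100A10 0.59 ± 0.04, CRIP2 1.38 ± 0.17, RALGPS2 -0.65 ± 0.07), and oxidative phosphorylation genes for 5 of 23 and 0 (COX5A 0.41 ± 0.07). Naive genes fell for 8 of 19 and rose for 2 (FOXP1 -0.99 ± 0.07, BACH2 -1.11 ± 0.09), and BCR signalling genes for 7 of 17 and 2 (CD79A -0.29 ± 0.04). Plasma and secretory genes rose for 7 of 15 and fell for 2 (PRDM1 1.02 ± 0.18). Atypical genes rose for 4 of 16 and fell for 4 (DUSP4 0.89 ± 0.12, LILRB1 -1.09 ± 0.09), with a median of 0.11, a mean of 0.02 and camera's direction down. Of 11 T cell markers CD2 (-1.01 ± 0.19), CD8A (-0.83 ± 0.20) and CD4 (-0.94 ± 0.28, in 5 of 6 animals) fell and CD3G rose in 4 of 6 (0.44 ± 0.12). The call of CD8A was lost without female 2 (-0.80) and female 3 (-0.74). Of 5 NK cell markers CST7 fell (-0.55 ± 0.09) and NKG7 rose in 5 of 6 animals (0.73 ± 0.19). The call of NKG7 was lost without female 1 (0.70), female 3 (0.57) and female 4 (0.65) and with heavy contigs of 3 or more UMIs (0.63). Of 3 monocyte markers TYROBP and LYZ (-0.54 ± 0.10) fell and CST3 rose (0.77 ± 0.17). CD4, CD3G and CST3 were named after their values were seen, and their calls were lost with 1 animal left out. CD4 was at -0.85 without female 2, -0.94 without male 1 and -0.72 without male 2, CD3G at 0.40 without female 1 and 0.32 without female 3, and CST3 at 0.52 without female 3. Adjusted over the list alone, the counts of risen and fallen genes were 11 and 0 for immediate early, 9 and 0 for TNF family receptors and NF-kB, 7 and 3 for homing, 10 and 4 for memory and 12 and 0 for oxidative phosphorylation. They were 3 and 8 for naive, 8 and 3 for plasma, 5 and 5 for atypical and unchanged for BCR signalling. Camera called 7 lists: immediate early (adjusted p = 8.05e-06, and 0.231 with an estimated correlation), TNF family receptors and NF-kB and oxidative phosphorylation (both 7.38e-05, and 0.199 with an estimated correlation), memory (0.0036, and 0.231), naive (0.00601, and 0.231), BCR signalling (0.0264, and 0.255) and plasma (0.0317, and 0.255).

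The count of 1298 genes within memory cells was 28 without the animal as a block, 824 by DESeq2, 818 without female 1 and 794 without female 3. With animal and memory subtype both as blocks, a setting chosen after seeing the data and run on 27 pairs of sums, 261 genes were called, 193 of them shared with the 1298. Most animals gave several pairs, which counted as separate replicates, so the p-values of this fit may be too small. EYA2 (1.18), MGLL (0.54), TTN (-1.85), TYROBP (-1.57), CD72 (-0.81), FOXP1 (-0.46), BACH2 (-0.42), CRIP1 (0.27), S100A10 (0.28), DUSP2 (0.56), JUN (0.34) and CST7 (-0.47) kept their calls in it, whereas ITGA4 (0.10), CCR7 (0.03), CD70 (0.15), DUSP4 (0.18), LYZ (-0.18) and COX5A (0.07) lost theirs. CADM1, SSPN, TANC2, ZBTB38, AEBP1, TCL1A and RFLNB did not pass its filter on low counts and were not tested in it. CD79A (0.00424, adjusted p = 0.984 by edgeR) and LTB (-0.267, adjusted p = 0.0262) changed direction.

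To compare the isotypes of switched cells, IgA and IgG B cells other than antibody-secreting cells were compared in the 5 animals with 10 or more cells of each, the sums holding 15 to 770 cells. The classes lay in different subtypes, since 84 of 130 IgA cells and 156 of 1925 IgG cells were C-MBC 2, and 10 and 955 were CD11c+ MBC 1 or 2. JCHAIN, which links IgA into polymers, was at 543 ± 173 CPM in IgA cells and 75.4 ± 51.1 in IgG cells (3.13 ± 0.22 SE, n = 5, adjusted p = 2.6e-11 by edgeR's quasi-likelihood test). Among genes that met the naming rule, the other largest increases in IgA cells were those of THY1 (2.62 ± 0.36), SEPTIN3 (2.60 ± 0.34), SIT1 (2.47 ± 0.39), AIRE (2.36 ± 0.42) and the complement receptor gene CR1 (2.18 ± 0.20). PTCH1, the hedgehog receptor gene, fell from 58.6 CPM in IgG to 3.35 in IgA cells (-4.22 ± 0.49), where it had 3 UMIs. Over pooled counts that was 23.6-fold lower, with an exact 95% Poisson interval of 8.07 to 114 that covers counting error only, and 14.9-fold without female 3, with 2 UMIs (4.14 to 123). RASL11A (-4.13 ± 0.60) had 2 UMIs in IgA cells and was 20.4-fold lower (5.64 to 168). Its UMIs lay in female 3, without which it was at least 6.89-fold lower against a floor of 3 UMIs over the group. The transcription factor gene TOX2 (-3.28 ± 0.27), LUZP1 (-3.12 ± 0.49), TNFRSF18 (-3.02 ± 0.56) and LDB2 (-2.90 ± 0.31) were lower as well, and all 6 in 5 of 5 animals, as the naming rule required. Without female 3 LUZP1 kept 1 UMI in IgA cells (32.7-fold lower, 5.86 to 1289.9) and TNFRSF18 0 (at least 7.13-fold lower). Of 6477 genes 858 were called, 357 higher and 501 lower in IgA cells. The atypical list fell for 10 of 13 members and rose for 1. ITGAX fell from 553 to 113 CPM (-2.34 ± 0.17), and NR4A2 (-1.85 ± 0.15), SOX5 (-1.72 ± 0.17) and the Src family kinase gene FGR (-1.77 ± 0.23) were lower too. Immediate early and stress genes fell for 12 of 16 and rose for 0 (FOS -1.66 ± 0.15), and marginal zone genes fell for 3 of 5 and rose for 0 (CD1C -1.15 ± 0.15, DTX1 -2.75 ± 0.43). Plasma and secretory genes rose for 4 of 12 and fell for 0 (DERL3 1.84 ± 0.23). Ribosomal protein genes rose for 9 of 20 and fell for 0 (RPS12 0.38 ± 0.07, RPL32 0.34 ± 0.07), and transitional genes for 2 of 6 and 0 (VPREB3 1.33 ± 0.35 in 4 of 5 animals, CD38 0.65 ± 0.18). Both of these calls were lost without 1 animal, VPREB3 at 1.21 without female 1 and 0.99 without male 2, and CD38 at 0.48 without female 3. Memory genes went both ways, 6 of 18 higher and 5 lower (CRIP2 1.86 ± 0.25, ANXA4 -1.60 ± 0.21, GPR183 -1.07 ± 0.13, ANXA2 -0.76 ± 0.14). So did homing genes, 3 of 13 higher and 4 lower (ITGA4 1.59 ± 0.18, ITGB2 -1.83 ± 0.16), and BCR signalling genes, 2 of 17 higher and 5 lower (CD22 -1.72 ± 0.23, LYN -0.88 ± 0.11). Of the T cell markers CD3D rose (1.41 ± 0.23), while CD3E was at -0.09 ± 0.39 (adjusted p = 0.93 by edgeR), and HBA of red cells rose in 4 of 5 animals (1.33 ± 0.25). Lower in IgA cells were CST7 of NK cells (-1.48 ± 0.34, in 4 of 5 animals) and LYZ of monocytes (-1.33 ± 0.38, in 5 of 5). CST7 lost its call without female 3, at -0.85, and LYZ without female 4, at -1.08.

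Adjusted over the list alone, the counts of higher and lower genes in IgA cells were 1 and 11 for atypical, 5 and 0 for plasma, 11 and 0 for ribosomal protein genes and 4 and 1 for transitional. They were 8 and 8 for memory, 4 and 6 for BCR signalling, and as over all genes for immediate early, marginal zone and homing. Camera called immediate early (adjusted p = 1.07e-07, and 0.269 with an estimated correlation), atypical (2.77e-05, and 0.256), ribosomal protein genes (0.000365, and 0.554), plasma (0.0104, and 0.26), marginal zone (0.0259, and 0.26) and transitional (0.0276, and 0.26). It also called oxidative phosphorylation (0.0483, and 0.554 with an estimated correlation), where edgeR called 0 of 23 genes, 4 had an unadjusted p under 0.05 and COX5B was at 0.38 ± 0.14 (adjusted p = 0.07). The count of 858 genes was 481 after leaving out cells with UMIs of T, NK or myeloid genes, 437 of them shared, 226 without the animal as a block and 561 without female 3.

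Within C-MBC 2 alone, a setting chosen after seeing the data with 12 to 39 cells per sum in the same 5 animals, 50 of 2910 genes were called. Of the 858 genes 564 were tested there, and 40 were among the 50. Immediate early and stress genes were lower in IgA cells for 10 of 14 members and higher for 0, and 12 were lower when adjusted over the list alone. FOS was at -1.58 ± 0.15 and DUSP2, a phosphatase gene named after its values were seen, at -2.94 ± 0.19, each lower in 5 of 5 animals. JCHAIN (1.00, adjusted p = 0.00355 by edgeR), CRIP2 (1.07) and NR4A2 (-1.01) kept their calls. Of the atypical list 1 of 6 measured genes was lower, and ITGAX was at 0.54 (adjusted p = 0.582 by edgeR). Calls were lost for SEPTIN3 (0.63 ± 0.32), SIT1 (0.42 ± 0.34), DERL3 (0.61 ± 0.25), CD1C (-0.14 ± 0.21), GPR183 (-0.20 ± 0.13), ITGA4 (0.30 ± 0.18) and LYN (-0.11 ± 0.12). They were also lost for CD38 (0.48 ± 0.23), CD3D (0.86 ± 0.29) and HBA (0.45 ± 0.24), and with the SEs of these small sums a lost call does not show that a difference was absent. CR1 (-0.24), VPREB3 (-0.995), ANXA2 (0.59), ITGB2 (0.00702) and RPL32 (-0.11) lost theirs with the opposite sign, and RPS12 was lower (-0.27, adjusted p = 0.00683 by edgeR).

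To compare the receptors of the classes, repertoire measures were taken per animal. IGHV divergence was 4.76 ± 0.828 differences per 100 bases in switched and 1.37 ± 0.306 in unswitched cells (mean ± SD, n = 6). The difference of 3.39 ± 0.641 was positive in 6 of 6 animals (exact two-sided sign-flip permutation p = 0.03125, the smallest that 6 animals allow). The references came from unswitched cells, so that unswitched cells carrying one were at 0 by construction. With references from Naive B cells 1 alone, a setting chosen after seeing the data, the difference within memory subtypes was 3.17 (exact permutation p = 0.03125). A reference sequence was found for 79.3% of switched and 83.0% of unswitched cells on average, but for 25% and 35.7% in female 4, without which the difference was 3.26. Kappa light chains were carried by 46.7% ± 5.84 of switched and 50.5% ± 4.91 of unswitched cells. The difference of -3.82 ± 4.58 percentage points was negative in 6 of 6 animals (exact permutation p = 0.03125) and ranged from -11.8 in female 1 to -0.217 in female 4. Without female 1 it was -2.23 (exact permutation p = 0.0625, the smallest that 5 animals allow). With both classes thinned to the same number of cells, 2.60% ± 1.47 of switched and 0.976% ± 0.857 of unswitched cells belonged to clones of 2 or more cells. This difference of 1.62 ± 1.27 was positive in 6 of 6 animals (exact permutation p = 0.03125). Without thinning, the difference was 0.100 (exact permutation p = 0.781). Expansion was rare, since 121 of 10159 clones held 2 or more cells, the largest held 5 and 5 clones held both classes. Heavy CDR3 regions averaged 16.1 ± 0.320 amino acids in switched and 15.7 ± 0.318 in unswitched clones, with a difference of 0.339 ± 0.471 that was positive in 4 of 6 animals (exact permutation p = 0.125).

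**Figure D3:**
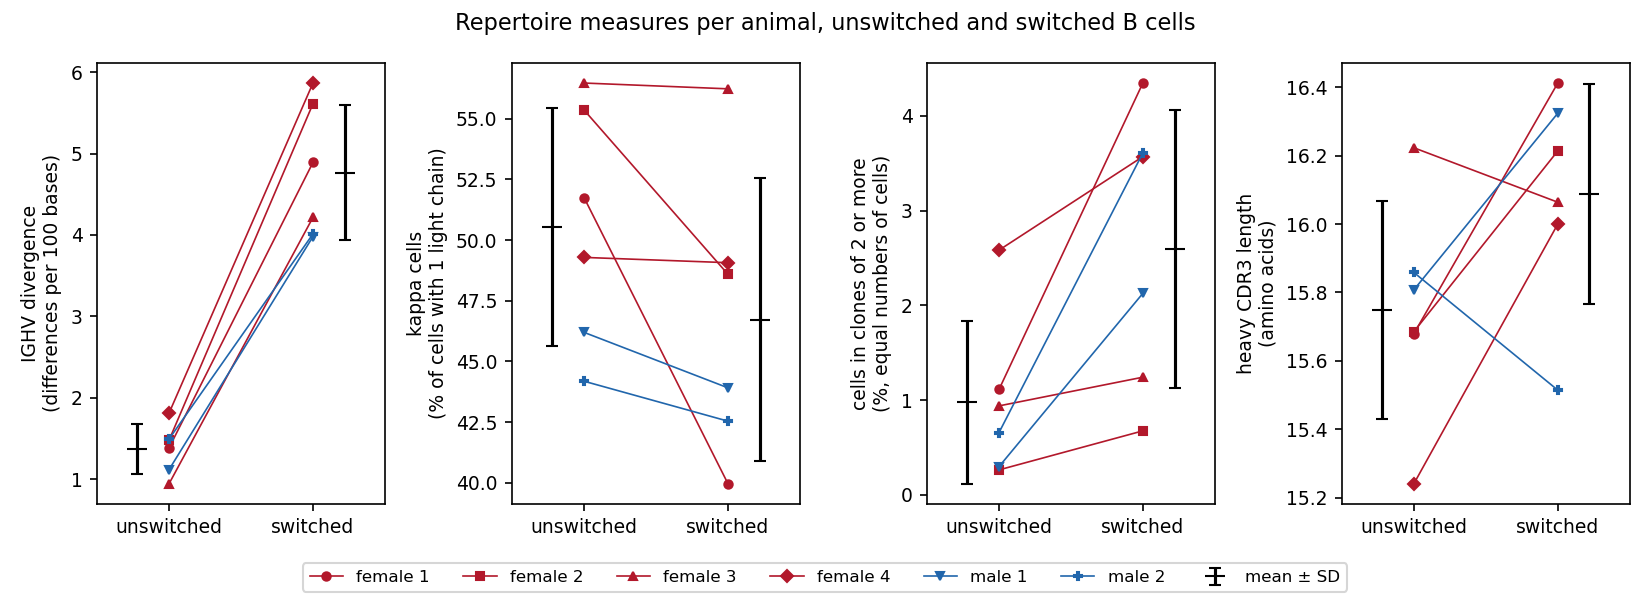
IGHV divergence (differences per 100 bases), kappa cells (% of cells with 1 light chain), cells in clones of 2 or more (%, at equal numbers of cells) and heavy CDR3 length (amino acids) in unswitched and switched B cells, with a line per animal, females in red and males in blue, and the mean ± SD in black. Divergence and the clone share were higher in switched cells in 6 of 6 animals and the kappa share was lower in 6 of 6, while CDR3 length was higher in 4 of 6.

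IGHV usage was compared between the classes in distinct clones, over 102 genes in all. The most used genes were IGHV4-122 with 486 clones, IGHV4-173 with 473, IGHV3-103 with 471, IGHV4-169 with 445 and IGHV3-182 with 400. Of 72 genes tested, 6 were called by edgeR's quasi-likelihood test and 11 had an unadjusted p under 0.05. IGHV1-198 (1.29 ± 0.37) and IGHV4S16 (1.37 ± 0.43) were used more in switched clones, each in 4 of 6 animals. IGHV3-37 (-2.22 ± 0.71), IGHV3-124 (-1.50 ± 0.48), IGHV3-116 (-0.93 ± 0.30) and IGHV3-182 (-0.78 ± 0.27, lower in 5 of 6 animals) were used less, with adjusted p = 0.0454 by edgeR for IGHV3-182 and 0.0316 for the other 5. Leaving out any 1 animal left 0 or 1 of these calls, and DESeq2 and the fit without the animal as a block called 0. IGHV1-198 was at 0.82 without male 1 and 2.03 without female 3, IGHV3-124 at -0.71 without female 3, IGHV3-116 at -0.59 without female 1 and IGHV3-37 at -1.42 without male 1. IGHV3-37 had 3 switched clones against 57 unswitched ones, a share 5.71-fold lower (exact 95% Poisson interval 1.95 to 27.7). All 3 were in female 1, without which the share was at least 3.17-fold lower against a floor of 3 clones over the group. Of 7 IGHV families, 0 passed the exact sign-flip permutation test, with or without adjustment. Family IGHV3 made up 30.6% of switched and 36.1% of unswitched clones, a difference of -5.45 that was negative in 5 of 6 animals (exact permutation p = 0.0938, adjusted p = 0.219). Family IGHV4 made up 52.0% and 48.4% (adjusted p = 0.394 by the exact permutation test).

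To ask whether the light chain class went with gene expression, unswitched cells with a kappa and with a lambda chain were compared. Cells of all subtypes were pooled, antibody-secreting cells included. Over all classes, kappa chains were carried by 56.8% of M-MZL BC and 57.2% of Activated B cells, against 43.9% of Naive B cells 1. Whether this mix of subtypes accounts for the differences below was not tested. Only 5 of 9235 genes were called, and 395 had an unadjusted p under 0.05. JCHAIN was at 176 ± 122 CPM in kappa and 90.6 ± 42.7 in lambda cells (0.99 ± 0.13 SE, higher in 5 of 6 animals, adjusted p = 1.1e-05 by edgeR's quasi-likelihood test, and 0.61 without female 1). GZMB, which encodes the protease granzyme B, was at 21.8 CPM in kappa and 105 ± 168 in lambda cells (-1.33 ± 0.23, lower in 4 of 6 animals, adjusted p = 0.0054 by edgeR). It was at -1.25 without female 2, where the call was lost, and at -0.78 without female 4. The haemoglobin gene HBA (0.79 ± 0.15, higher in 5 of 6 animals), ITGAX (-0.21 ± 0.04, lower in 5 of 6) and VPREB1, a surrogate light chain gene (-0.70 ± 0.14, lower in 6 of 6), had adjusted p of 0.011, 0.032 and 0.032 by edgeR. All 3 calls were lost without female 2, without male 1 and without male 2, and that of ITGAX also without female 1. HBA was at 0.79 without female 2, 0.76 without male 1 and 0.36 without male 2, VPREB1 at -0.68, -0.67 and -0.55, and ITGAX at -0.18, -0.23 and -0.20, with -0.19 without female 1. Of the plasma and secretory list 1 of 14 genes was higher and 3 when adjusted over the list alone, among them MZB1 (0.31 ± 0.07). Camera called this list higher (adjusted p = 0.0176, and 0.559 with an estimated correlation), NK cell markers lower (0.0176, and 0.559) and platelet and red cell markers higher (0.0149, and 0.559). Adjusted over the list alone, 3 of 5 NK cell markers were lower, with NKG7 at -0.98 ± 0.22. DESeq2 and the fit without the animal as a block called 0 genes, leaving out cells with UMIs of T, NK or myeloid genes left 1, and heavy contigs of 3 or more UMIs 3. No filter on low counts gave 25. Without female 2 there were 2 calls and without male 1 there were 3.

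Males and females were compared over all B cells, a comparison that holds batch as well as sex. The Y-linked genes RPS4Y1 (1530 ± 67.1 CPM), DDX3Y (347 ± 89.3), RPS4Y2 (208 ± 15.2), UTY (161 ± 4.01), USP9Y (50.7 ± 1.61), EIF1AY (55.5 ± 10.1) and KDM5D (21.5) were expressed in the 2 males. These genes were between 0 and 0.596 CPM on average in the 4 females. RPS4Y1 and RPS4Y2 are near-identical copies between which counts are uncertain. Lower in the males were LST1 (-3.25 ± 0.36 SE), the stress-associated protein gene SERP1 (-3.02 ± 0.25, adjusted p = 0.0022 by edgeR's quasi-likelihood test) and SPN, which encodes CD43 (-2.42 ± 0.33). So were CITED2 (-2.31 ± 0.32), the mitochondrial gene ATP6 (739 against 2458 CPM, -1.73 ± 0.24) and PITPNA (-1.72 ± 0.22). Without male 1, where the lone male was assumed to vary like the females, all 6 calls were lost, with LST1 at -2.95, SERP1 at -2.93, SPN at -2.71, CITED2 at -2.87, ATP6 at -1.72 and PITPNA at -1.68. Those of SPN, CITED2, ATP6 and PITPNA were also lost without female 1 and without female 3, with ATP6 at -1.67 and -1.79, and all but that of SERP1 without male 2, with LST1 at -3.63. Without female 4 those of CITED2 (-2.34) and PITPNA (-1.75) were lost. Beside ATP6, mitochondrial UMIs per cell were lower in the males in C-MBC 1 (medians 1.33% and 1.39%, against 1.75% to 2.71% in the females). In CD11c+ MBC 1 they were at 1.61% and 1.72%, against 1.98% to 3.07%. The 2 antibody-secreting cells of male 1 went the other way, at 6.99%. KDM5D, at 21.4 and 21.5 CPM in the males and 0 in the females, lost its call without either male. Of 11180 genes 38 were called, 25 higher and 13 lower in males, and 1976 had an unadjusted p under 0.05. In simulated data of this design 0% of 2-fold and 74.2% of 4-fold changes were recovered, so smaller differences were mostly not detectable. None of the lists' genes was called over all genes by edgeR, although 7 of 20 naive genes had an unadjusted p under 0.05. Of these, 4 were higher when adjusted over the list alone (FOXP1 0.87 ± 0.21, BACH2 1.08 ± 0.29). Adjusted over the list alone, 3 of 7 platelet and red cell markers were lower, with TUBB1 at -2.83 ± 0.59 and PF4 at -2.55 ± 0.61. Camera called ribosomal protein genes higher (adjusted p = 0.00303, and 0.995 with an estimated correlation) and NK cell markers lower (0.00758, and 0.995), with NKG7 at -1.94 ± 0.63 and KLRD1 at -2.18 ± 0.68. The count of 38 was 634 by DESeq2, all 38 among them, 67 with no filter on low counts, 14 without female 1, 136 without female 2, 18 without female 3, 7 without male 1 and 18 without male 2.

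The males also held other shares of subtypes and classes. Activated B cells made up 10.6% of B cells in males and 3.73% in females, CD11c+ MBC 2 5.12% and 14.3%, and C-MBC 1 7.74% and 10.9%, without overlap between the sexes. Such separation was found for 3 of 12 subtypes, where chance gives 13.3%, and no exact permutation test could go below p = 0.0667 with 15 splits (smallest adjusted p = 0.533). The number without overlap was 5 without female 4, where chance gives 20%, and 6 without male 2, where 1 male was left and chance gives 40%. Switched cells made up 13.5% of cells with 1 heavy chain in males and 30.6% ± 5.46 in females (exact permutation p = 0.0667).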

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

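The tests of a difference between the sexes were chosen after the class comparisons had been seen, and the exchanges of class labels were planned. Of 58 groups of animals examined for a value far from the others, 3 had one, where chance gives about 1 in 20. Antibody-secreting cells made up 3.37% of the B cells of female 4 and 0.251% to 0.459% in the other females. Those 19 cells had a median of 3696 UMIs and 1.54% ribosomal UMIs, and 52.6% carried a BCR contig. The 14 of female 3 were similar, at 3966.5 UMIs, 1.47% and 64.3%. The 10 and 4 of females 1 and 2 had medians of 19801 and 16908.5 UMIs, 4.89% and 15.1%, and all carried a contig. Whether cell quality adds to the share in female 4 was not tested. The log2 difference of EYA2 between switched and unswitched cells was 5.65 in female 4 and 2.51 to 3.50 in the other 5 animals, and within memory cells 4.31 against 2.04 to 2.53. Female 4 also had the fewest B cells, 563.

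The difference between kappa and lambda cells was itself tested between the sexes, which coincide with the batches. By edgeR's quasi-likelihood test of the interaction, EGR1 differed by -0.622 on the log2 scale (male minus female, adjusted p = 0.000669), GZMB by 2.24 (adjusted p = 0.00872) and HBA by 1.23 (adjusted p = 0.00872), in 2 males and 4 females. In all 4 genes were called there, with 383 at an unadjusted p under 0.05. For switched against unswitched cells edgeR called 0 interactions (623 at an unadjusted p under 0.05), within memory cells 4 (648) and for IgA against IgG 0 (408), and no other tool was run.

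Signal also lay outside the main comparisons. In the cluster annotated as contamination, 74.5% ± 9.86 of cells carried a BCR contig (mean ± SD, n = 6 animals), 282 B cells held 2 productive heavy chains, and 2455 BCR barcodes lay outside the expression table.

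When class labels were exchanged within animals, 3 of the 6 comparisons of genes met the planned limit, a share under 0.05 of exchanges calling as many. Their 1 of 32 is the smallest share possible and was not adjusted over the comparisons, so it argues against chance without excluding it. For switched against unswitched cells 1 of 32 exchanges, the real one, called as many as 2416 genes, and the highest other called 1. Within memory cells it was also 1 of 32, with 1298 genes against at most 586 in the others, that exchange having changed female 4 alone. For IGHV usage 1 of 32 reached 6 calls, against 0 in the others, although leaving out any 1 animal left 0 or 1 call. For the subtypes 1 of 25 reached 33497, against at most 1179, which says nothing of chance, since they were annotated on the same expression values. For IgA against IgG the 16 exchanges are too few for a share under 0.05, and 1 reached the 858 genes, against 0 in the others. For kappa against lambda 3 of 32 exchanges called as many as the real 5, with a highest other of 8, so chance cannot be excluded.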

How the results depend on the processing

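Settings added after seeing the data were leaving out Naive B cells 2 and 3, the block by animal and memory subtype, C-MBC 2 only for IgA against IgG and divergence within memory cells with references from Naive B cells 1, and all others were planned. Of the alternatives for single named genes, 887 of 933 kept direction and side of the threshold for switched against unswitched cells, 869 of 949 within memory cells and 719 of 805 for IgA against IgG. So did 733 of 773 for kappa against lambda, 690 of 736 for the sexes and 69 of 140 for IGHV genes. The fit without the animal as a block called 104 genes for switched against unswitched cells, 28 within memory cells, 226 for IgA against IgG, 0 for kappa against lambda, 0 IGHV genes and 18532 for the subtypes. The pairing changed every such count by more than 1.5 times. Pairing by animal does not enter the comparison of the sexes. With animal and memory subtype as blocks 261 genes were called within memory cells, CD79A reversed to 0.00424 (adjusted p = 0.984 by edgeR) and LTB to -0.267 (adjusted p = 0.0262), in a fit with fewer cells per sum. That fit counted several pairs of the same animal as separate replicates. In C-MBC 2 only, where IgA and IgG sums held fewer cells and fewer genes were tested, 50 genes were called for IgA against IgG. There CR1 reversed to -0.24, FCER2 to -1.17, VPREB3 to -0.995, ANXA2 to 0.59, ITGAX to 0.54, ITGB2 to 0.00702, CXCR5 to 0.00713, LTB to -0.54, CD40 to -0.38, RPS12 to -0.27 and RPL32 to -0.11.

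Other settings moved some counts by more than 1.5 times, and the cause was not tested. DESeq2 called 824 genes within memory cells, 0 for kappa against lambda, 634 for the sexes and 0 IGHV genes. Leaving out cells with UMIs of T, NK or myeloid genes gave 481 genes for IgA against IgG and 1 for kappa against lambda. No filter on low counts gave 25 genes for kappa against lambda and 67 for the sexes. For kappa against lambda, immunoglobulin and unnamed genes kept in library sizes gave 1, heavy contigs of 3 or more UMIs 3, and batch 2 only 8. IGHV calls were 0 with 50 or more clones per gene, in batch 2 only and with the heavy chain of most UMIs, and 1 with all barcodes. Camera with an estimated correlation called 0 lists, where 27 were called with a preset one and 29 by fry. In batch 2 only, with 4 animals and a smallest possible exact p of 0.125, the divergence difference was 3.74, that of the kappa share -4.75 and that of expanded clones 1.23. The kappa difference was -3.81 with all barcodes (exact permutation p = 0.0625) and -3.91 with heavy contigs of 3 or more UMIs (0.0938). The difference in expanded clones was 1.39 with such contigs (exact permutation p = 0.0625) and 0.100 without thinning (0.781).

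Leaving out each animal in turn gave 1569 to 2327 genes for switched against unswitched cells, 794 to 1291 within memory cells and 561 to 779 for IgA against IgG. It gave 2 to 6 for kappa against lambda, 7 to 136 for the sexes, 24325 to 31413 for the subtypes, 0 to 1 for IGHV genes and 0 to 0 for IGHV families. The difference in divergence was 3.24 to 3.57, in the kappa share -4.55 to -2.23, in expanded clones 1.27 to 1.91 and in CDR3 length 0.255 to 0.475. The number of subtypes without overlap between the sexes was 3 to 6 of 12, where chance gives 20% without a female and 40% without a male. GZMB in the IgA comparison, which was not called, ranged from -2.65 without female 1, where it reversed, to 1.18 without female 4. The comparison of IgA and IgG with 30 or more cells per sum was not run, because fewer than 3 animals had such sums. In simulated data of each design, 0% of 2-fold changes were recovered for the sexes, with 2 males, 25% for IGHV usage and 68.1% for IgA against IgG, with IgA sums of as few as 15 cells.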

Other observations

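The tests on Naive B cells 2 within animals and on their switched share were chosen after the results had been seen. So were that of UMIs per cell in subtypes with many cells lacking a heavy chain, and both tests of the males' switched share. The others were chosen before. Activated B cells stood out among the unswitched subtypes for IRF4 (795 ± 359 CPM), a transcription factor induced by receptor signalling, and for FCRL5 (564 ± 211 CPM). Of these cells 57.2% ± 13.4 carried kappa chains (mean ± SD, n = 6 animals). Antibody-secreting cells had the proliferation gene MKI67 at 921 ± 680 CPM in 3 animals. IGHD was the constant gene of 30.9% ± 18.6 of heavy chains in M-MBC 1 and 30.3% ± 17.9 in Naive B cells 1, against 10.7% ± 10.5 in M-MZL BC and 2.28% ± 2.10 in C-MBC 1. The cluster annotated as contamination expressed the B cell gene MS4A1 at 543 ± 177 CPM beside GZMB (512 ± 759), GNLY (354 ± 498), CD3E (305 ± 169), IL7R (277 ± 231) and CD3D (211 ± 78.2). Within memory cells, the genes whose class difference varied with sex included APOD, CD69 and CCL5, named after their values were seen.

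Naive B cells 2 and 3 held few ribosomal transcripts and few BCR contigs, and the cell types transferred by the authors were B intermediate for 402 and 21 of these cells and B naive for 41 and 103, against 144 and 1469 of Naive B cells 1. Shallow sequencing of these cells could not be judged over all 6 animals, where 70.47% ± 37.4 (SD) of 176 Naive B cells 1 at or under their pooled median UMIs carried a contig. With the median of each animal instead, 3 animals had 10 or more such cells. Of these 625 cells 96.3% ± 0.878 carried a contig, against 42.8% ± 7.15 of Naive B cells 2 of the same animals. Lower expression depth is therefore excluded as the whole cause in those 3 animals. They were female 1 and the 2 males. In the males Naive B cells 2 were not shallower, with median UMIs of 3661 and 4073 against 3481 and 2985.5 in Naive B cells 1. Female 3, with 217 Naive B cells 2 at a median of 1916 UMIs, had 4 such Naive B cells 1 and was not covered. Damage with loss of cytoplasmic RNA stays open, since the median log2 ratio of 8 cytoplasmic transcripts against Naive B cells 1 was -1.15 ± 0.891 and below 0 in 5 of 6 animals, male 2 excepted at 0.299. A gathering of cells of several subtypes by their quality may add to it, in line with 18.4% ± 8.42 switched cells among Naive B cells 2 in 4 animals, against 0.455% in Naive B cells 1. No biological explanation was tested.

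A light chain without a heavy chain was found in 30.05% ± 11.1 of light-chain-bearing CD11c+ MBC 2, 28.0% ± 12.1 of C-MBC 1 and 24.3% ± 7.27 of C-MBC 2 cells, against 4.48% ± 2.80 of Naive B cells 1. Naive B cells 2, with 18.4% switched cells, had 30.3% ± 5.57 in 4 animals and Naive B cells 3 18.2% in 1, and the cause there stays open. In the first 3, lower expression depth of the subtype as a whole is excluded as the cause. Their median expression UMIs per cell were 1.54 ± 0.0928 times those of Naive B cells 1. BCR UMIs of these subtypes were not compared with those of Naive B cells 1, so lower depth in the BCR library stays open. UMIs of the cells lacking a heavy chain were not measured apart, so lower depth of those cells stays open. Fewer heavy chain UMIs in switched cells may be a cause in those 3, as their median was 0.451 ± 0.0493 times that of unswitched cells of the same subtypes in 6 of 6 animals (exact permutation p = 0.03125). That of light chains was 0.913 ± 0.134 times (exact permutation p = 0.1875).

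Switched cells were fewer in the males, at 13.5% of cells with 1 heavy chain against 30.6% in the females. Shallower BCR libraries as the whole cause would leave subtype shares, taken from the expression libraries, alike. CD11c+ MBC 2, C-MBC 1 and C-MBC 2 together, as annotated by the authors, made up 16.4% of B cells in males and 29.9% ± 3.07 in females, without overlap. These values argue against that cause but cannot exclude it. Heavy contigs had a median of 6 and 8 UMIs in males 1 and 2 and of 16, 6, 13 and 14 in females 1 to 4. Female 2, at 6 like male 1, had 28.3% switched cells against 13.3% in male 1, but is 1 animal. Expression libraries of the males were shallower too (mean of median UMIs per cell 4048.5 against 6190.5), and whether this changed the annotation was not tested. Counting every cell with a light chain and no heavy chain as switched would give 24.5% and 39.9%. B cells with neither chain stayed out of this count. Sex and batch cannot be told apart here, and the exact permutation p of 0.0667 is the smallest that 15 splits allow.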
